A study of Mus musculus with 20 samples.

How the data were processed

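NK cells were isolated from the spleens of 20 mice, and total RNA was amplified, labelled with Cy3 and hybridised to Agilent whole-genome mouse arrays, 1 array per mouse and 5 mice per group. The deposited scanner files hold intensity values, and per the submitters' processing notes they were made with Agilent Feature Extraction 9.5.3.1. The column used for the main setting, the processed signal, is a background-subtracted spot intensity per the file headers, not scaled between arrays. The series also carries a table of processed values on the log2 scale, which the authors describe in its header as log2 values in which a control and a ptaquiloside array holding many outliers were replaced by the mean of the other mice of the group, followed by a t-test with a false discovery rate and a 2-fold limit. Set against the scanner values, its columns equal the log2 processed signal plus 19.93 with no scaling between arrays. The first 4 control columns hold control mice 2 to 5 and the last one is their mean. The fourth ptaquiloside column holds mouse 5 and the last one is the mean of the first 4. Column medians run from 22.8 to 23.7. Because some of its columns are averages of others, the table entered only as an alternative. The scanner columns used as flags and names were of unit other, per the file headers, and marked control spots, outlier spots and spots well above background.

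For the main setting, the log2 processed signal minus the array's 75th percentile over non-control spots was computed. Control spots and spots marked as outliers were left out, spots of the same probe were averaged, and probes well above background on at least 5 of the 20 arrays were kept. Of 41174 probes 25097 were named through their accession in the reference table of gene names given with the data, and 16077 were not matched there and kept the name in the file. One probe per gene name was used, the one with the highest mean over all arrays, which left 17481 genes, 17342 of them with a value on all 20 arrays (279 missing values). Of the values of named genes, 60 belong to genes with several tested probes, and in 11 of these, in 9 genes, a probe pointed the other way; the single-probe values given in the text stand for the brightest probe. Coordinates are those of the probes as the file headers and columns give them, on mm9 (NCBI37), and no annotation of exons or introns was used. A gene below background on every array of a group was given as an estimated fold, the brighter group's mean over all its arrays against the mean of the dim group. On each dim array the higher of the probe's own signal and the lowest signal well above background was used. This is not a lower limit, since arrays below background enter both means.

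Differences were tested with limma 3.58.1 (statmod 1.5.0, data.table in version 1.17.8, R 4.3.3), with 1 mean per group fitted to all 20 arrays, moderated variances, two-sided tests and Benjamini-Hochberg adjustment over all genes at 0.05. The 5 comparisons between groups, the interaction and the F-test over the 4 groups were each adjusted separately. Gene lists, 31 in number with 667 entries of which 618 had a tested gene, cover stress and immune pathways and markers of other spleen cells. Each was tested with camera at a preset correlation between genes of 0.01, adjusted over the 31 lists of a comparison. Beside it stand camera with an estimated correlation, and fry, which asks whether a list's genes move one way on balance. Of 65 list calls with the preset correlation, 0 held with the estimated correlation and 0 passed fry, whose smallest adjusted p was 0.475. The comparisons, tests, lists, alternatives and the rule for named genes were set before the data were examined, apart from those that the text names as added later. The rule names Mt1 and Mt2 in every comparison, genes past the threshold with all arrays of a group on the same side of the other group's mean, the 10 such genes with the smallest p where fewer passed, and up to 4 members of each list discussed. It favours genes with a stable direction, so their counts of slides are not a separate test.

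The slide, the mouse number and the order of scanning coincide, and all arrays carry the same scan day, so the mouse number as a block is the slide as a block. The tests were tried on simulated data for ptaquiloside against control over the 17481 genes. With each gene's spread over the 20 arrays, 1.49%, 13.4% and 65.2% of genes shifted by 0.5, 1 and 2 on the log2 scale were recovered with 1 false call. With the spread left without the array of ptaquiloside mouse 4 and without slide differences, 16.4%, 58.2% and 89.4% were recovered with 3 false calls. Both settings drew all 20 arrays and fitted them without a block, so the second gives no recovery rate for the blocked fit without that array. The shifted list was called in both settings, and 0 other lists were. Genes were drawn independently there, so the simulation cannot show how often lists of correlated genes are called falsely. Regroupings of the real arrays called up to 21 lists. Alternatives included normexp background correction (offset 50), median centring, quantile normalization, other filters on dim probes, all probes, outlier spots kept, the slide as a fixed or random block, array weights, a trended and robust prior, only the arrays compared, the deposited table, the methods' t-test and leaving out each array in turn. The methods' t-test was run on the 43379 spots of unscaled log2 signal with equal variances, on all 5 mice per group, with control mouse 1 and ptaquiloside mouse 4 replaced by means, and without them. The t-test, the removal of the dimmest arrays together with a block, the list tests with single arrays left out, and the comparison of control with all treated mice were added after the data had been seen. Permutation tests of the mean of Mt1 and Mt2 were exact for 5 against 5 mice and within slides. All 20 arrays were used in the main setting, including the dim array of ptaquiloside mouse 4.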

Results

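Gene expression was measured in natural killer (NK) cells, the cytotoxic lymphocytes of innate immunity, isolated from the spleens of 20 male C57BL/6 mice on 20 single-colour microarrays. The mice had received water (control), ptaquiloside at 5.3 mg/kg, selenium at 1.3 mg/kg, or both compounds by gavage on each of 14 days, with 5 mice per group and a different donor mouse for each array. Ptaquiloside is the carcinogenic glucoside of bracken fern, and selenium is the trace element built into selenoproteins. The cells were collected without being bound themselves, by removing other spleen cells on magnetic columns, so remaining B cells, T cells or myeloid cells would contribute RNA. The 75th percentile of the processed signal lay between 45.5 and 133 scanner units on 19 arrays and at 10.5 on the array of ptaquiloside mouse 4. On that array 36.3% of the spots were well above background, against 51.7% to 60.8% on the others, and its correlation with the other arrays across probes was 0.634 to 0.759, whereas the other 19 arrays correlated with each other at 0.938 to 0.990. Each of the 5 slides carried 1 mouse of every group with the same mouse number, and a group always occupied the same position on the slide, so position and treatment cannot be told apart. The number of arrays limits the precision of every value.

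**Figure D1:**
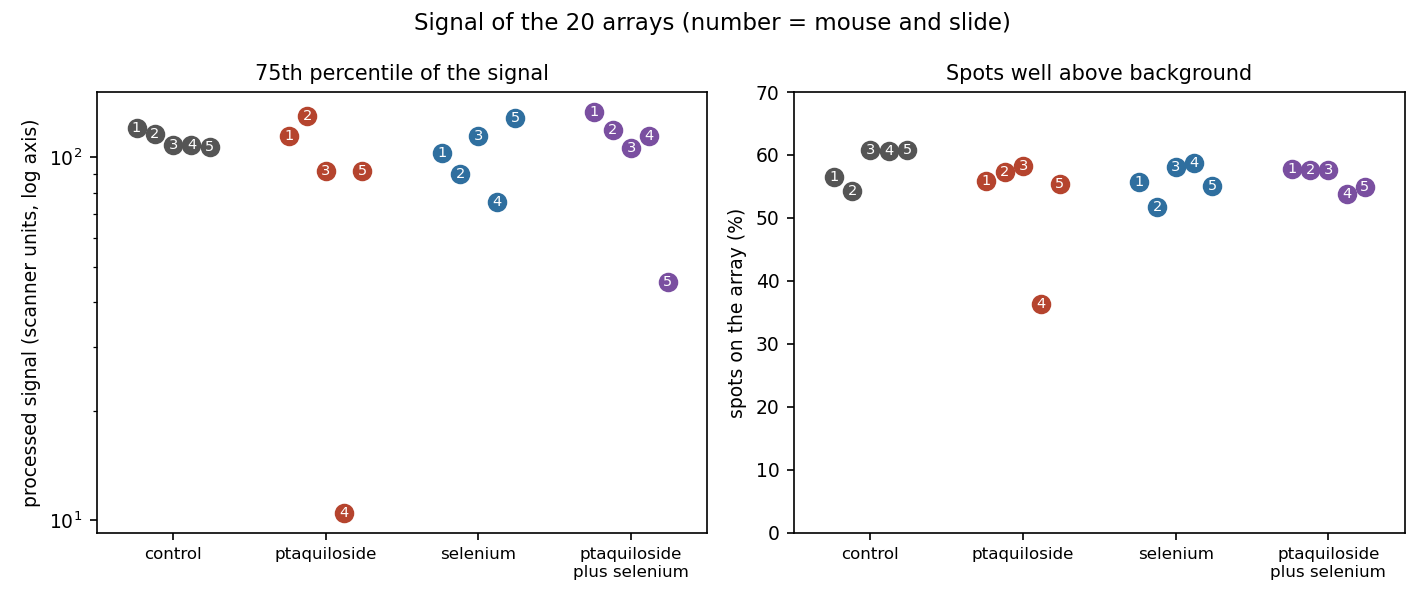
The 75th percentile of the processed signal in scanner units on a log axis (left) and the percentage of spots well above background (right) for each of the 20 arrays, arranged by group, with the mouse number written in each point. The array of ptaquiloside mouse 4 has a 75th percentile of 10.5 and 36.3% of its spots above background, below all other arrays.

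Single genes are described below with their values, because limma called 0 of the 17481 genes tested in each of the 5 comparisons between groups, in the interaction and in the test for any difference among the 4 groups. At an unadjusted p under 0.05 there were 262 genes for ptaquiloside against control, 183 for selenium against control, 40 for both compounds against control, 418 for both compounds against ptaquiloside, 103 for both compounds against selenium, 206 for the interaction and 170 among the 4 groups, each below the 874 genes that independent tests would give by chance. With the slide as a block the calls stayed at 0 and the unadjusted counts were 465, 330, 71, 720, 198, 364 and 367 in the same order. Without the array of ptaquiloside mouse 4 there were also 0 calls, with 261, 453, 102, 488, 290, 399 and 289 genes at an unadjusted p under 0.05. With the block and without that array the calls were 0 and the counts 421, 947, 236, 791, 642, 727 and 671, and without mouse 5 of the group given both compounds as well they were 660, 1434, 467, 873, 1040, 1063 and 1028, again with 0 calls. Selenium against control was then above the number expected by chance in both settings, and both compounds against selenium, the interaction and the 4 groups in the second. The methods' t-test on unscaled signals likewise called 0 of 43379 spots in each comparison with control on all mice, with 611, 1095 and 431 spots at an unadjusted p under 0.05 for ptaquiloside, selenium and both compounds. Because every slide held all groups, log2 differences with the slide as a block equal those without it for the 17342 genes measured on all 20 arrays.

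The comparison of ptaquiloside with control addressed what the toxin alone did to the isolated cells, and most of the 10 genes with the smallest p were higher in the treated mice. Spint1, a membrane-bound inhibitor of serine proteases (probe at chromosome 2, 119074929 to 119074988), averaged -0.83 ± 0.90 (SD, n = 5) on the log2 scale with ptaquiloside and -2.81 ± 0.92 (SD, n = 5) in control, a 3.92-fold difference. Ahrr, the repressor of the aryl hydrocarbon receptor (chromosome 13, 74348566 to 74348612), was higher by 2.07 ± 0.52 (SE) and was above background on 3 of 5 arrays in both groups. Gsdme, a pore-forming gasdermin of lytic cell death (chromosome 6, 50157436 to 50157495), was higher by 1.27 ± 0.34 (SE), and Ccno, a cyclin of multiciliated cells (chromosome 13, 113780810 to 113780869), by 0.90 ± 0.30 (SE). All 4 were higher on 5 of 5 slides, with an adjusted p of 0.802 from limma. On slide 4 these counts rest on the dim array of ptaquiloside mouse 4. There Ahrr (-1.18) had its highest ptaquiloside signal and Ccno (-0.95) its lowest, while Gsdme (0.41) lay within the other ptaquiloside arrays. Among the other genes with the smallest p, Tcte3 (1.29), Xpnpep3 (1.02), Chad (0.82) and Pramel12 (0.75) were higher. Btk, a kinase of B cell receptor signalling, was lower (-0.85, and -0.54 without the array of ptaquiloside mouse 4), and so was the transcriptional co-regulator Hcfc1 (-1.05), of whose 3 probes 1 pointed the other way (0.13). Chad (-0.81) had its highest ptaquiloside signal on the array of ptaquiloside mouse 4 and Hcfc1 (-2.69) its lowest. None of the differences named here passed the threshold.

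Metallothioneins, small metal-binding proteins that the series followed up at the protein level, had higher mean signals in ptaquiloside mice for all 4 genes measured, with Mt3 turning to -0.03 under median centring of the arrays. Mt1 (chromosome 8, 96704011 to 96704070) averaged 4.41 ± 0.93 (SD, n = 5) against 3.72 ± 1.26 (SD, n = 5) in control, a log2 difference of 0.70 ± 0.68 (SE). Mt2 (chromosome 8, 96697371 to 96697430) averaged 5.83 ± 1.06 (SD, n = 5) against 5.00 ± 1.59 (SD, n = 5), a difference of 0.83 ± 0.79 (SE). Mt4 differed by 0.66 and Mt3 by 0.20, and without the array of ptaquiloside mouse 4 by 0.32 and 0.07. The adjusted p of Mt1 and Mt2 was 0.802, and a two-sided exact permutation test of the mean of both genes gave p = 0.357 (5 against 5 mice). Within slides the mean of both was higher with ptaquiloside on 3 of 5, by -0.16 to 2.27, and the exact permutation p was 0.25 where 5 slides allow none below 0.0625. As a list the 4 genes passed the test with the preset correlation (median difference 0.68, adjusted p = 0.0393, higher on 4 of 5 slides, -0.21 to 1.35), which was lost at adjusted p = 0.784 with an estimated correlation. The call also ended without control mouse 3 (0.51, adjusted p = 0.111), 4 (0.40, 0.130) or 5 (0.68, 0.0698) and without ptaquiloside mouse 1 (0.44, 0.146), 2 (0.83, 0.0590), 3 (0.58, 0.106) or 5 (0.69, 0.117). The deposited table replaced the arrays of control mouse 1 and ptaquiloside mouse 4 by averages. Without both arrays the limma difference was 1.52 for Mt1 and 1.68 for Mt2, with an adjusted p of 0.995 for each. Leaving out control mouse 1 alone, whose array was not dim, moved Mt1 to 1.18 and Mt2 to 1.38 (adjusted p of 0.908 for each). Mice numbered 1 lay above the rest by 2.09 for Mt1 and 2.50 for Mt2. These fits had no slide block, so with control mouse 1 out and ptaquiloside mouse 1 kept, part of that slide difference enters the values. Mt1 stood at 0.41 without control mouse 3, and Mt1 and Mt2 at 0.43 and 0.38 without control mouse 4 and at 0.46 and 0.42 without ptaquiloside mouse 1.

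**Figure D2:**
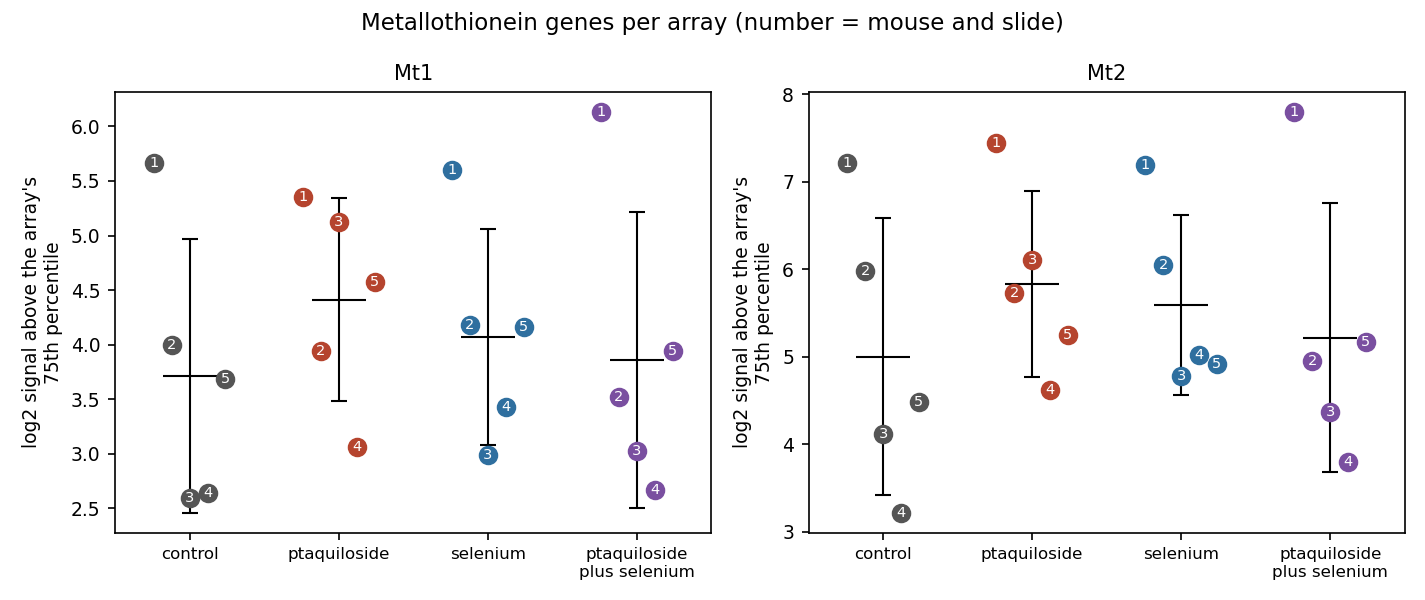
Mt1 (left) and Mt2 (right) per array as log2 signal above the array's 75th percentile, by group, with the mouse number in each point, black lines for group means and bars for the SD of 5 mice. Mice numbered 1 have the highest values in each group, with a mean of both genes between 6.39 and 6.97 against 2.93 to 5.62 in all other mice.

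Markers of neutrophils, erythroid cells and B cells were lower in ptaquiloside mice than in control. Medians of the other cell marker lists ran from -0.36 for dendritic cells to 0.05 for innate lymphoid and stromal cells, with T cells at -0.13, platelets at -0.06 and plasma cells at -0.04. Of 17 neutrophil markers 15 were lower (median -0.47, adjusted p = 0.0129), including the protease Mmp9 (-0.78), the secreted Retnlg (-0.83) and Chil3 (-0.60) and the calcium-binding S100a8 (-1.13), and the list was lower on 5 of 5 slides (-1.21 to -0.03). Of 16 erythroid markers 13 were lower (median -0.40, adjusted p = 0.0393, lower on 4 of 5 slides, -1.19 to 0.73), among them carbonic anhydrase Car1 (-0.89), Ermap (-0.72), the transcription factor Gata1 (-0.40) and Slc25a37 (-0.42, of whose 2 probes the other gave 0.24). Of 16 B cell markers 14 were lower (median -0.53, adjusted p = 0.0300, lower on 3 of 5 slides, -2.24 to 0.73), among them the antigen receptor subunit Cd79b (-1.23), Fcrla (-1.23), Ms4a1 and the transcription factor Spib (-0.85). NK receptors and adaptors were lower for 27 of 33 genes (median -0.25, adjusted p = 0.0374, lower on 2 of 5 slides, -0.94 to 0.36). For these 4 lists the adjusted p was 0.784 with an estimated correlation. NK cytotoxic effectors were lower for 11 of 18 genes without a call (median -0.25, adjusted p = 0.146, -1.30 to 0.37 within slides), and p53 and DNA damage genes for 15 of 26 (median -0.12, adjusted p = 0.462, -1.17 to 0.41 within slides). Of 6 genes of the aryl hydrocarbon response 4 were higher (median 0.25, adjusted p = 0.255, higher on 4 of 5 slides, -0.46 to 0.54), among them the target Tiparp (0.61), while Ahr (-0.77), the receptor itself, and its partner Arnt (-0.39) were lower. Arnt turned to 0.03 with normexp background correction, and only 2 of its 4 tested probes were lower (-0.42 to 0.33 over the 4). Adjusted over the list alone, Ahrr passed the threshold and 0 genes did in the other lists named here.

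The array of ptaquiloside mouse 4 set several of these group values. After scaling, genes of the dimmest decile by mean signal had a median of 3.17 above its slide mates, and those of the brightest decile a median of -1.47. Without that array NK receptors stood at 0.09 (adjusted p = 0.185), NK effectors at 0.08 (0.598), p53 genes at 0.18 (2.83e-04, now called higher) and the aryl hydrocarbon response at 0.32 (0.0163, now called), both at adjusted p = 0.325 with an estimated correlation. Neutrophil markers kept their call at -0.26 (0.00429), erythroid markers at -0.47 (1.96e-04) and B cell markers at -0.49 (0.00735), at adjusted p = 0.401, 0.401 and 0.652 with an estimated correlation. Single genes moved with it, S100a8 to -0.30, Chil3 to -0.22, Cd79b to -0.54, Fcrla to -0.65, Slc25a37 to -0.14, Ahr to -0.27, Tiparp to 0.98 and Arnt to 0.13. Without control mouse 2 Car1 stood at -0.58 and Ermap at -0.38, without ptaquiloside mouse 1 Gata1 at -0.25 and Arnt at -0.66, and without ptaquiloside mouse 5 Ms4a1 at -0.57 and Spib at -0.55. The neutrophil call ended without ptaquiloside mouse 5 (-0.39, adjusted p = 0.0843). The erythroid call ended without control mouse 2 (-0.29, 0.528) or ptaquiloside mouse 2 (-0.45, 0.0590), 3 (-0.25, 0.338) or 5 (-0.38, 0.336). The B cell call ended without control mouse 1 (-0.46, 0.0507) or 5 (-0.34, 0.0946) or ptaquiloside mouse 2 (-0.59, 0.109) or 5 (-0.21, 0.478), and the median was -0.95 without ptaquiloside mouse 1. The call of the NK receptors also ended without control mouse 1 (-0.19, 0.136) or 2 (-0.08, 0.252) or ptaquiloside mouse 1 (-0.21, 0.0663), and NK effectors stood at -0.32 without control mouse 5 (0.0403 with the preset correlation, the estimated one not having been run there). Median p53 difference was -0.26 without ptaquiloside mouse 1 and that of NK effectors -0.39 without mouse 2. Median centring in place of the 75th percentile moved the median of all genes by -0.23 in this comparison, taking the median of NK receptors to -0.48, of NK effectors to -0.49, of p53 genes to -0.36, of erythroid markers to -0.64, of metallothioneins to 0.45 and of the aryl hydrocarbon response to 0.0180. Quantile normalization gave 0.0481 for the last and -0.26 for p53 genes. With normexp background correction B cell markers stood at -0.21, erythroid markers at -0.18, NK receptors at -0.16, metallothioneins at 0.35, the aryl hydrocarbon response at 0.14 and p53 genes at -0.00433.

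Selenium alone was compared with control to show what supplementation did by itself, and the isolated cells of these mice had higher signals for genes of cell division and of the interferon response. Which cells carried these signals was not tested, and some arrays were low or high for cell cycle genes together with neutrophil and erythroid markers. Mean scores of the 3 lists were -0.64, -0.39 and -0.99 in selenium mouse 5, and 0.70, 0.72 and 0.68 in mouse 1 of the group given both compounds. In the cell cycle list 32 of 33 genes were higher (median 0.62, adjusted p = 2.71e-24, adjusted p = 0.0675 with an estimated correlation), including cyclin Ccne1 (0.71), the replication helicase subunits Mcm7 (0.51) and Mcm3 (0.58) and the mitotic Cdca8 (0.79). All 33 interferon-stimulated genes were higher (median 0.42, adjusted p = 2.37e-17, and 0.0675 with an estimated correlation), among them the antiviral oligoadenylate synthetases Oas3 (1.19), Oas2 (1.13) and Oas1a (1.00) and Usp18 (1.10 ± 0.33 SE), a brake on interferon signalling. Heat shock genes were higher for 17 of 18 (median 0.26, adjusted p = 2.81e-04, and 0.302 with an estimated correlation). Members include Stip1 (0.47), Hsph1 (0.49), Hspd1 (0.40) and Hsp90ab1 (0.35). The aryl hydrocarbon response had 3 genes higher and 3 lower (median 0.42, adjusted p = 3.67e-04, and 0.0675 with an estimated correlation), with Ahrr (1.74), the quinone reductase Nqo1 (1.06) and Tiparp (0.93) above control and Ahr (-0.37) below it. Those 3 higher genes passed the threshold adjusted over the list alone, and 0 genes did in the other lists of this comparison. The median of the aryl hydrocarbon response fell to 0.07 and that of the cell cycle list to 0.35 with normexp background correction. Ahr stood at -0.23 without selenium mouse 1.

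Markers of other leukocytes were lower with selenium. Of 16 B cell markers 14 were lower (median -0.83, adjusted p = 3.36e-11, and 0.0893 with an estimated correlation), led by the transcription factor Ebf1, Fcer2a (-1.23) and Ms4a1 (-1.14). Of 13 T cell markers 12 were lower (median -0.38, adjusted p = 5.73e-07, and 0.0675 with an estimated correlation). Members include Cd8b1 (-1.98), Cd8a (-1.21), Cd5 (-0.98) and Trat1 (-0.50). Of 20 macrophage and monocyte markers 15 were lower (median -0.38, adjusted p = 6.93e-07, and 0.0675 with an estimated correlation). Members include the mannose receptor Mrc1 (-1.48), Cd14 (-0.97), the red pulp macrophage factor Spic (-0.87) and lysozyme Lyz2 (-0.41). Dendritic cell markers were lower as well (median -0.35, adjusted p = 3.53e-05, and 0.0893 with an estimated correlation), whereas neutrophil markers (0.57, 0.00127, and 0.211) and platelet and megakaryocyte markers (0.19, 0.00451, and 0.645) were higher. NK receptors and adaptors (median 0.14, adjusted p = 0.0195) and NK cytotoxic effectors (0.20, 0.0327) were slightly higher, both at adjusted p = 0.869 with an estimated correlation. Without selenium mouse 2 both calls ended, the median of the receptors falling to 0.03 (adjusted p = 0.764) and that of the effectors staying at 0.14 (0.550). Both calls also ended without control mouse 4 (0.11, 0.188, and 0.20, 0.0998) or 5 (0.11, 0.166, and 0.11, 0.301), that of the receptors without control mouse 3 (0.13, 0.0614) and that of the effectors without selenium mouse 1 (0.21, 0.0526) or ptaquiloside mouse 4 (0.20, 0.0690). The neutrophil call ended without selenium mouse 3 (0.29, 0.185), with a median of 0.36 without control mouse 3 and 0.88 without selenium mouse 5. The platelet call ended without control mouse 4 (0.14, 0.0998) or 5 (0.10, 0.405) or selenium mouse 1 (0.13, 0.259). With normexp background correction B cell markers stood at -0.28, T cell markers at -0.18 and macrophage markers at -0.20. Selenoproteins and genes of selenium handling showed no common direction (16 higher, 11 lower, median 0.02, adjusted p = 0.487, -0.06 to 0.17 within slides), and the median was 0.08 under median centring and 0.00117 with normexp background correction. Leaving out single arrays moved it between -0.02 and 0.06. Examples are Selenow (0.22), the mitochondrial thioredoxin reductase Txnrd2 (0.26), selenocysteine lyase Scly (0.16, of whose 2 probes the other gave -0.03) and the elongation factor Eefsec (0.22). Without selenium mouse 2 these 4 stood at 0.09, 0.16, 0.08 and 0.10. Without control mouse 2 Selenow stood at 0.37, Scly at 0.25 and Eefsec at 0.39, without control mouse 4 Selenow at 0.15 and Eefsec at 0.09, without control mouse 3 Scly at 0.10 and without selenium mouse 5 Eefsec at 0.35.

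Among single genes Spint1 was higher by 2.39 with selenium and Hic1, a transcriptional repressor under control of p53 (chromosome 11, 74978107 to 74978166), by 1.88 ± 0.42 (SE), each on 5 of 5 slides with an adjusted p of 1.00 from limma. Gsdme (1.20), Ccno (1.12), the ubiquitin ligase subunit Asb2 (0.84), the tubulin Tuba8 (0.82) and the mannose phosphate mutase Pmm1 (0.64) were higher and the insulin receptor Insr lower (-0.95). Mt2 differed by 0.59 ± 0.79 (SE) and Mt1 by 0.36 ± 0.68 (SE), less than the spread between mice. In the order Mt2 and Mt1 they stood at 1.14 and 0.84 without control mouse 1, 0.36 and 0.07 without control mouse 3, 0.14 and 0.09 without control mouse 4 and 0.19 and -0.03 without selenium mouse 1, and Mt1 at 0.63 without selenium mouse 3.

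Within slides the selenium minus control median was above 0 on 5 of 5 slides for interferon-stimulated genes (0.05 to 1.11), heat shock genes (0.04 to 0.49) and the aryl hydrocarbon response (0.14 to 0.85), and on 4 of 5 for the cell cycle list (-0.27 to 1.22). It was below 0 on 5 of 5 slides for T cell markers (-1.06 to -0.12) and macrophage markers (-0.63 to -0.14), and on 4 of 5 for B cell markers (-1.98 to 0.15). Single mice moved some medians by over 1.5 times without ending a call. Without control mouse 5 the interferon median was 0.26 (adjusted p = 8.19e-13), that of T cell markers -0.25 (1.65e-04) and that of macrophage markers -0.19 (5.35e-04), without control mouse 1 the last was -0.57 (7.75e-10), and without selenium mouse 2 the interferon median was 0.27 (4.73e-15). The heat shock median was 0.17 without control mouse 3 (adjusted p = 4.65e-04), 0.15 without control mouse 4 (0.00780) and 0.15 without selenium mouse 2 (4.63e-04).

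**Figure D3:**
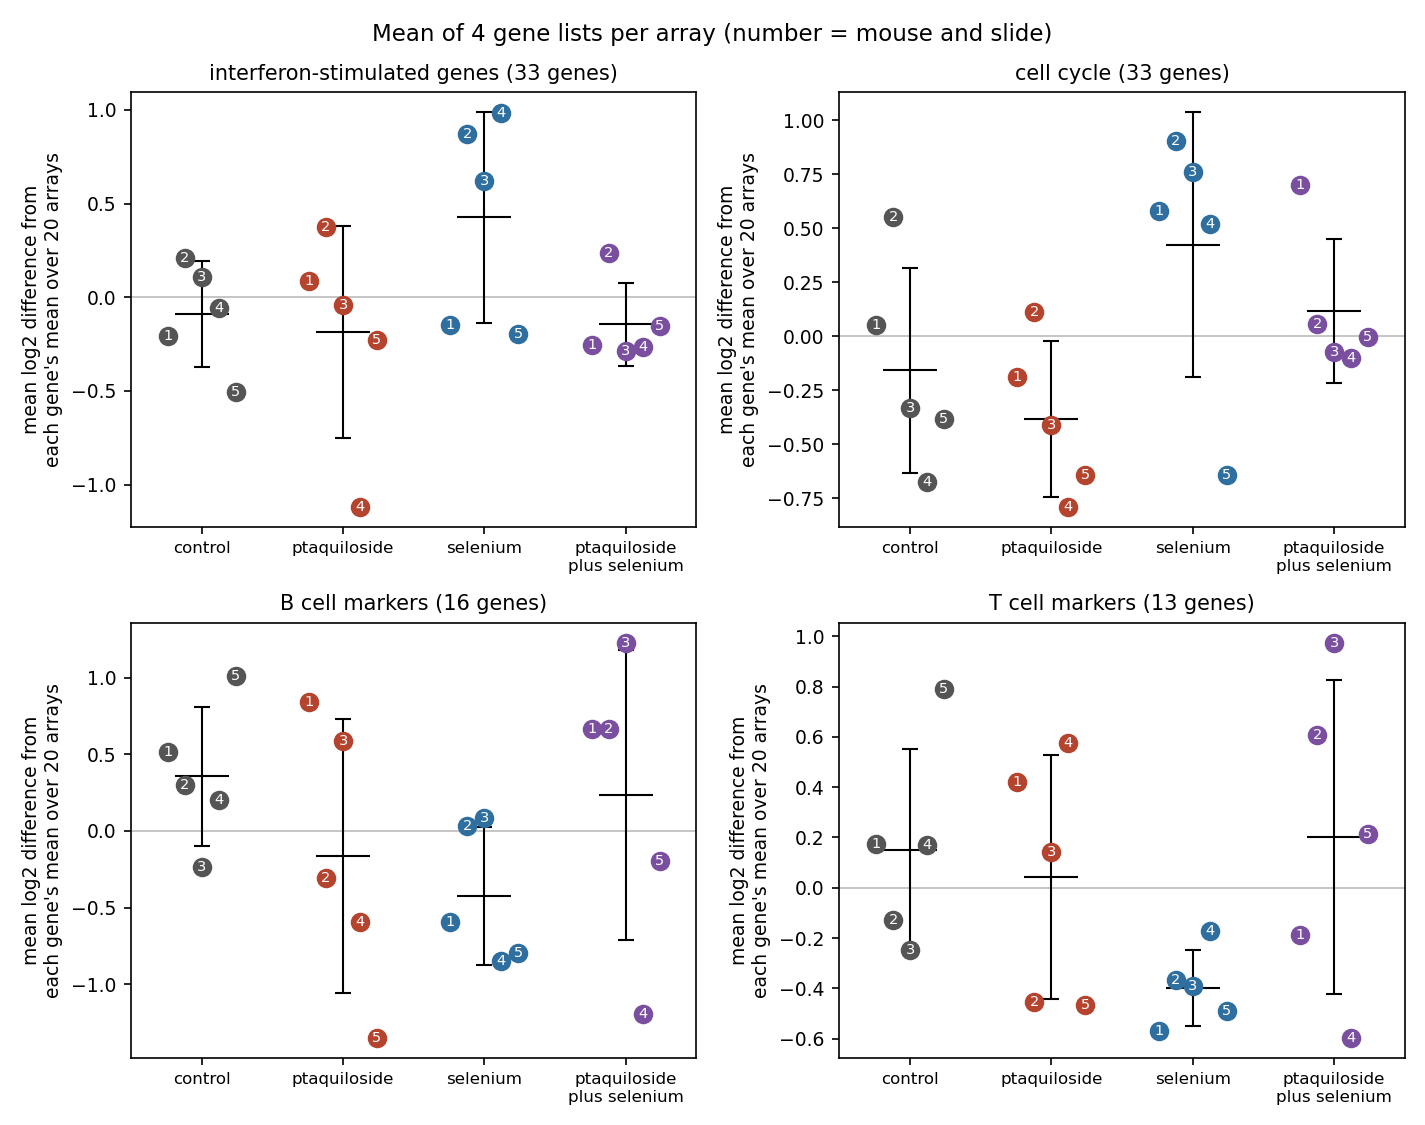
Mean log2 difference from each gene's mean over the 20 arrays, for interferon-stimulated genes, cell cycle genes, B cell markers and T cell markers, per array and by group, with the mouse number in each point, black lines for group means and bars for the SD of 5 mice. In the selenium group all 33 interferon-stimulated genes have a higher group mean than in control (median 0.42), and B cell markers have a lower one for 14 of 16 genes (median -0.83).

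Mice given both compounds were compared with control to show the combined effect. The cell cycle list was higher for 32 of 33 genes (median 0.25, adjusted p = 3.31e-09, and 0.653 with an estimated correlation). Members include the nucleotide reductase Rrm2 (0.76), Birc5 (0.58), the topoisomerase Top2a (0.55) and the proliferation marker Mki67 (0.53). The aryl hydrocarbon response was higher for 4 of 6 genes (median 0.27, adjusted p = 2.15e-04, and 0.0695 with an estimated correlation), with Ahrr (1.84), Tiparp (0.67) and Nqo1 (0.50) above and Ahr (-0.36) below control. All 13 platelet and megakaryocyte markers were lower (median -0.24, adjusted p = 3.22e-06, and 0.497 with an estimated correlation), such as the chemokine Ppbp (-0.50), Vwf (-0.26) and Gp5 (-0.25). Of 12 basophil and mast cell markers 10 were lower (median -0.38, adjusted p = 4.22e-05, and 0.223 with an estimated correlation), such as the IgE receptor subunit Fcer1a (-0.58), the cytokine Il4 (-0.57) and the proteases Cpa3 (-0.52) and Mcpt8 (-0.41). Heat shock genes were higher for 15 of 18 (median 0.16, adjusted p = 0.0107, and 0.653 with an estimated correlation). Members include Hsph1 (0.45), Hspa1b (0.34), Stip1 (0.29) and Hsp90ab1 (0.18). Adjusted over the list alone, Ahrr passed the threshold and 0 genes did in the other lists. The aryl hydrocarbon response stood at 0.07, platelet markers at -0.15 and basophil markers at -0.21 with normexp background correction. Gp5 ranged from -0.41 without mouse 3 of the combined group to -0.15 without its mouse 4 and -0.13 without its mouse 5. Hspa1b turned to -0.17 without mouse 1 of that group and stood at 0.01 without control mouse 4, 0.54 without control mouse 1 and 0.78 without mouse 5 of that group. Without that mouse 5 Hsph1 stood at 0.69, Nqo1 at 0.29, Hsp90ab1 at 0.28, Cpa3 at -0.27 and Vwf at -0.16, without its mouse 1 Hsph1 at 0.23 and without its mouse 4 Ppbp at -0.33. Without control mouse 2 Mcpt8 stood at -0.25 and Vwf at -0.18, without control mouse 4 Birc5 at 0.35 and Mki67 at 0.34, and without control mouse 5 Stip1 at 0.17.

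Spint1 (2.22), Ahrr, Gsdme (1.38), Hic1 (1.08), Ccno (0.93) and the membrane protease St14 (0.59) were higher with both compounds than in control on 5 of 5 slides, at an adjusted p of 1.00 from limma. Esm1, a secreted proteoglycan (chromosome 13, 114008204 to 114008263), was not well above background on any of the 5 control arrays. Its mean signal was 2.88-fold higher with both compounds, where 3 of 5 arrays measured it. Single arrays ran from -4.92 to -2.04 with both compounds and from -6.05 to -4.43 in control. The basophil receptor Cd200r3 (-0.65), Creb3l4 (-0.97) and the endothelin receptor Ednra (-0.91, of whose 2 probes the other gave 0.60) were lower. Mt2 (0.22 ± 0.79 SE) and Mt1 (0.14 ± 0.68 SE) differed by less than their standard errors. Mt2 and Mt1 turned to -0.23 and -0.13 without control mouse 4, -0.00686 and -0.14 without control mouse 3 and -0.43 each without mouse 1 of the combined group. They stood at 0.77 and 0.63 without control mouse 1, and at 0.43 and 0.35 without mouse 3 and 0.57 and 0.44 without mouse 4 of that group. Mt2 was 0.46 without control mouse 2 and 0.09 without control mouse 5, and Mt1 0.23 without mouse 2 of that group.

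Erythroid markers (median 0.25, adjusted p = 0.0286, and 0.683 with an estimated correlation) and neutrophil markers (0.42, 0.0485, and 0.653) were higher with both compounds than in control, and dendritic cell (-0.13, 0.0207, and 0.653) and macrophage markers (-0.14, 0.0268, and 0.653) lower. Each of these 4 calls ended without control mouse 3, at medians of 0.13 (adjusted p = 0.214), 0.30 (0.278), -0.07 (0.214) and -0.10 (0.0573), and without at least 1 mouse of the combined group. Erythroid markers stood at 0.0227 and dendritic cell markers at -0.07 with normexp background correction. Within slides the cell cycle median ranged from -0.51 to 0.69 (above 0 on 4 of 5), the aryl hydrocarbon response from -0.31 to 1.03 (4 of 5), heat shock genes from -0.03 to 0.27 (3 of 5), platelet markers from -0.65 to 0.30 (below 0 on 3 of 5) and basophil markers from -0.70 to 0.09 (below 0 on 4 of 5). The cell cycle call ended without mouse 1 of the group given both compounds (0.12, adjusted p = 0.102), and the median was 0.45 without control mouse 2 and 0.13 without control mouse 4. The platelet call ended without mouse 4 of that group (-0.14, 0.0609), with a median of -0.13 without control mouse 2 and -0.36 without control mouse 5. The heat shock call ended without control mouse 4 (0.08, 0.178) or 5 (0.11, 0.0528) or mouse 1 (0.08, 0.600) or 2 (0.12, 0.0528) of the combined group. The aryl hydrocarbon median was 0.06 without mouse 5 of the combined group (0.00534).

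Both compounds against ptaquiloside alone compares mice given the toxin with and without selenium. It shares the 5 ptaquiloside arrays with ptaquiloside against control, so list differences of opposite sign in these comparisons are not independent. Cell cycle genes were higher for 31 of 33 (median 0.57, adjusted p = 4.09e-07). Members include Top2a (1.27), Mki67 (1.07), the microtubule regulator Stmn1 (0.96) and Rrm2 (0.92). Neutrophil markers were higher for 15 of 17 (median 0.70, adjusted p = 1.61e-04, and 0.636 with an estimated correlation). Members include S100a8 (1.62), S100a9 (1.07) and the granule proteins Ltf (1.21) and Camp (1.18). Erythroid markers were higher for 15 of 16 (median 0.57, adjusted p = 0.00103). Members include the blood group protein Rhd (1.48), Ermap (1.09), Slc25a37 (0.53, of whose 2 probes the other gave -0.24) and Gata1 (0.43). The cell cycle and erythroid lists had an adjusted p = 0.796 with an estimated correlation. All 4 metallothioneins were lower without a call (median -0.58, adjusted p = 0.112, lower on 5 of 5 slides, -0.88 to -0.05), with Mt4 at -0.63, Mt2 at -0.61 ± 0.79 (SE), Mt1 at -0.55 ± 0.68 (SE) and Mt3 at -0.13, the last turning to 0.06 under median centring and 0.03 with normexp background correction. Adjusted over the list alone, 0 genes passed in these 4 lists. With normexp background correction the medians were 0.26 for the cell cycle, 0.20 for erythroid markers and -0.26 for metallothioneins.

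Single genes with the smallest p were lower with the combination for the adaptor Git1 (-1.32), the complement receptor C5ar1 (-1.25), Spag1 (-1.18), the pyrimidine catabolic enzyme Dpys (-1.13), Unc93a (-1.03), Ccdc14 (-0.98) and the macrophage growth factor Csf1 (-0.63), and higher for Hcfc1 (1.04, of whose 3 probes 1 gave -0.23) and the lipid transfer protein Pitpnc1 (0.96), at an adjusted p of 0.823 from limma. The dim array of ptaquiloside mouse 4 entered these values. Git1 (-2.43), C5ar1 (-1.90), Dpys (-1.76) and Ccdc14 (-3.19) had their highest ptaquiloside signal on it, and Hcfc1 (-2.69) its lowest, whereas Csf1 (2.98) lay within the other ptaquiloside arrays. Myo16, an unconventional myosin (chromosome 8, 10634081 to 10634140), was not well above background on any of the 5 arrays of the combination. Its signal there was estimated as 3.23-fold lower than with ptaquiloside, where 3 of 5 arrays measured it. Without the array of ptaquiloside mouse 4 the group medians were 0.45 for the cell cycle (adjusted p = 1.04e-06), 0.68 for neutrophil markers (8.44e-05), 0.76 for erythroid markers (1.13e-06) and -0.59 for metallothioneins (0.136), while Top2a stood at 0.82, Stmn1 at 0.45, S100a8 at 0.79, S100a9 at 0.68, Ltf at 0.73, Slc25a37 at 0.25, Mt4 at -0.29, Mt1 at -0.89 and Mt3 at 0.00273. Without ptaquiloside mouse 1 Gata1 stood at 0.29, Mt1 at -0.32 and Mt2 at -0.21. Mt1 and Mt2 stood at -1.12 and -1.26 without mouse 1 of the combination, -0.35 and -0.40 without its mouse 3 and -0.26 each without its mouse 4, and Mt3 at 0.0109 without its mouse 1 and -0.27 without its mouse 5. Within slides the medians were 0.02 to 0.97 for neutrophil markers (5 of 5 above 0), -0.08 to 0.93 for the cell cycle and -0.18 to 1.69 for erythroid markers (4 of 5 each). The cell cycle median was 0.35 without mouse 1 of the combination (0.00167). The metallothionein list was called lower with the slide as a block (adjusted p = 0.0350, and 0.635 with an estimated correlation) and without mouse 1 of the combination (-0.88, 0.0249 with the preset correlation, the estimated one not having been run there), and its median was -0.26 without ptaquiloside mouse 1, -0.37 without mouse 3 and -0.26 without mouse 4 of the combination. Median centring moved the median of all genes by 0.20 in this comparison.

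Both compounds against selenium alone compares supplemented mice with and without the toxin. It shares the 5 selenium arrays with selenium against control, so list differences of opposite sign in these comparisons are not independent. Here interferon-stimulated genes were lower for all 33 genes measured (median -0.55, adjusted p = 4.46e-23, and 0.0531 with an estimated correlation). Examples are the oligoadenylate synthetase family members Oasl2 (-1.20) and Oas3 (-0.96), Rtp4 (-1.02, and -1.05 with the slide as a block, as a selenium array lacks it) and Usp18 (-0.89). Mean scores of the interferon list were 0.87, 0.62 and 0.98 in selenium mice 2, 3 and 4, against -0.15 and -0.20 in selenium mice 1 and 5. Cell cycle genes were lower for 32 of 33 (median -0.31, adjusted p = 3.02e-09, and 0.444 with an estimated correlation). Members include the mitotic kinase Cdk1 (-0.70), cyclin Ccna2 (-0.64), Mcm5 (-0.50) and Mcm7 (-0.35). All 13 platelet and megakaryocyte markers were lower (median -0.48, adjusted p = 5.97e-13, and 0.0531 with an estimated correlation). Members include Gp5 (-0.57), Vwf (-0.50) and Gp9 (-0.50). Of 12 basophil and mast cell markers 11 were lower (median -0.43, adjusted p = 9.84e-07, and 0.0531 with an estimated correlation). Members include the proteases Prss34 (-0.75), Mcpt8 (-0.68) and Cpa3 (-0.54) and the receptor subunit Fcer1a (-0.62). B cell markers were higher for 15 of 16 (median 0.63, adjusted p = 1.89e-09, and 0.194 with an estimated correlation). Members include Ebf1 (1.70), Pax5 (1.01) and Ms4a1 (0.98). T cell markers were higher for 12 of 13 (median 0.42, adjusted p = 4.13e-09, and 0.0531 with an estimated correlation). Members include Cd8b1 (1.87), Cd5 (1.15), Cd6 (0.79) and Cd3d (0.60). NK cytotoxic effectors (-0.23, adjusted p = 0.0142, and 0.683 with an estimated correlation) and NK receptors and adaptors (-0.13, 0.00557, and 0.735) were lower and macrophage markers higher (0.16, 0.00143, and 0.325). Both NK calls ended without mouse 5 of the combination, at -0.06 (adjusted p = 0.918) and -0.03 (0.942), and without selenium mouse 2, at -0.09 (0.326) and -0.02 (0.434). The macrophage median was 0.24 without mouse 1 of the combination, 0.26 without its mouse 2 and 0.32 without selenium mouse 5. With normexp background correction B cell markers stood at 0.30, T cell markers at 0.12, macrophage markers at 0.0474, the cell cycle at -0.20, platelet markers at -0.29, NK effectors at -0.11 and NK receptors at -0.06, and under median centring macrophage markers at 0.06 and NK receptors at -0.23. Without mouse 5 of the combination Cdk1 stood at -0.20, Mcm5 at -0.29 and Cpa3 at -0.29, without its mouse 3 Cd5 at 0.73 and Cd6 at 0.51, and without its mouse 4 Ms4a1 rose over 1.5 times. Without selenium mouse 5 Cdk1 stood at -1.06, Ccna2 at -1.01, Mcm7 at -0.56 and Prss34 at -1.22, without selenium mouse 2 Ccna2 at -0.40 and without selenium mouse 4 Rtp4 at -0.61. Adjusted over the list alone, 0 genes passed in these lists.

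The genes with the smallest p in that comparison included the steroid-metabolising Akr1c18 (1.10), the adaptor Gab1 (1.13), the egress receptor S1pr1 (0.98), the kinase Lrrk2 (0.85) and Insr (0.65) above selenium alone. Lgals3bp (-0.76), Cd200r3 (-0.73) and the hyaluronan-binding Itih1 (-0.65) lay below it, and the adjusted p was 1.00 for each from limma. Mt2 differed by -0.37 ± 0.79 (SE) and Mt1 by -0.21 ± 0.68 (SE), of whose 2 probes the other gave 0.16. They stood at -1.02 and -0.78 without mouse 1 of the combination, -0.16 and -0.01 without its mouse 3, -0.0172 and 0.08 without its mouse 4, 0.0284 and 0.17 without selenium mouse 1 and -0.57 and -0.49 without selenium mouse 3. Mt1 was -0.13 without mouse 2 of the combination and -0.37 without selenium mouse 4. Within slides the medians were -1.08 to 0.11 for interferon-stimulated genes and -0.88 to 0.30 for basophil markers (below 0 on 4 of 5 slides each), -0.82 to -0.06 for platelet markers (5 of 5), -0.88 to 0.66 for the cell cycle (3 of 5), -0.34 to 1.17 for B cell markers and -0.17 to 1.07 for T cell markers (above 0 on 4 of 5 each). The B cell median was 0.35 without mouse 3 of the combination (adjusted p = 0.00249) and 1.02 without mouse 4 (4.34e-19), and the cell cycle median was -0.19 without selenium mouse 2 (9.23e-05) and -0.58 without selenium mouse 5 (1.19e-24). Median centring moved the median of all genes by -0.10 here.

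Whether the ptaquiloside difference itself depended on selenium was tested as the interaction, in which a positive value means a more positive ptaquiloside difference in supplemented mice. B cell markers had a positive interaction for all 16 genes (median 1.01, adjusted p = 2.16e-07, and 0.402 with an estimated correlation). Members include Ebf1 (2.76), Fcrla (2.09), Ms4a1 (1.99) and Cd79b (1.90). T cell markers were positive for 11 of 13 (median 0.57, adjusted p = 2.94e-04, and 0.402 with an estimated correlation). Members include Cd8b1 (2.91), Cd5 (1.51), Cd3d (1.02) and Trat1 (0.80, of whose 2 probes the other gave -0.25). Interferon-stimulated genes were negative for 28 of 33 (median -0.50, adjusted p = 2.49e-05, and 0.526 with an estimated correlation). Members include Ifit2 (-1.63), Ifit3 (-1.27), Usp18 (-1.10) and the RNA sensor Dhx58 (-0.64). On single slides the median lay between 0.44 and 2.70 for B cell markers and between -0.78 and -0.10 for interferon-stimulated genes, each on the same side of 0 on 5 of 5 slides, and between -0.27 and 1.87 for T cell markers (4 of 5). Without ptaquiloside mouse 1 the T cell median was 0.86 (adjusted p = 4.72e-04), and without ptaquiloside mouse 4 Cd79b stood at 1.21 and Trat1 at 0.53. Normexp background correction gave medians of 0.39 for B cell markers, 0.22 for T cell markers and -0.33 for interferon-stimulated genes. Adjusted over the list alone, 0 genes passed in these 3 lists.

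The smallest p for the interaction of single genes were those of Asb2 (-0.95), Hic1 (-1.86), Insr (0.97, of whose 2 probes the other gave -0.36), Itih1 (-0.90), Spint1 (-2.14), the histone demethylase Kdm4d (-1.14), Tuba8 (-0.99), Chad (-1.16), Git1 (-1.51) and Lrrk2 (1.11), at an adjusted p of 0.997 from limma, and it was -1.20 for Mt2 and -0.91 for Mt1. Those 2 stood at -1.84 and -1.48 without mouse 1 of the combination and at -0.80 and -0.53 without selenium mouse 1, Mt2 at -0.75 without control mouse 4 and -0.79 without ptaquiloside mouse 1, and Mt1 at -1.40 without control mouse 1. Leaving out mouse 4 of the group given both compounds gave 1 call for the interaction, the transcript AK036773 (2.47, adjusted p = 0.0250, against 2.15 on all arrays). Across genes, the ptaquiloside difference without selenium and that with selenium correlated at 0.0997, where other regroupings of the arrays gave -0.653 to 0.720, the genes not being independent replicates. Leaving out single arrays moved it between -0.286 and 0.291, and it was below 0 without control mouse 2, ptaquiloside mouse 4, selenium mouse 5 or mouse 5 of the combination.

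Over all 4 groups the smallest p was that of Spint1 (3.80e-04), followed by Gsdme, Hic1, Insr, Ahrr, Oas1a, the potassium channel Kcnj2, Oas3, Asb2 and Ccno, with an adjusted p of 1.00 for each. Spint1 averaged -2.81 in control against -0.83, -0.42 and -0.58 with ptaquiloside, selenium and both, and Gsdme -0.90 against 0.37, 0.30 and 0.48. Ahrr averaged -4.22 against -2.16, -2.48 and -2.39, and Ccno -1.19 against -0.29, -0.07 and -0.26. These differences share the same 5 control arrays.

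**Figure D4:**
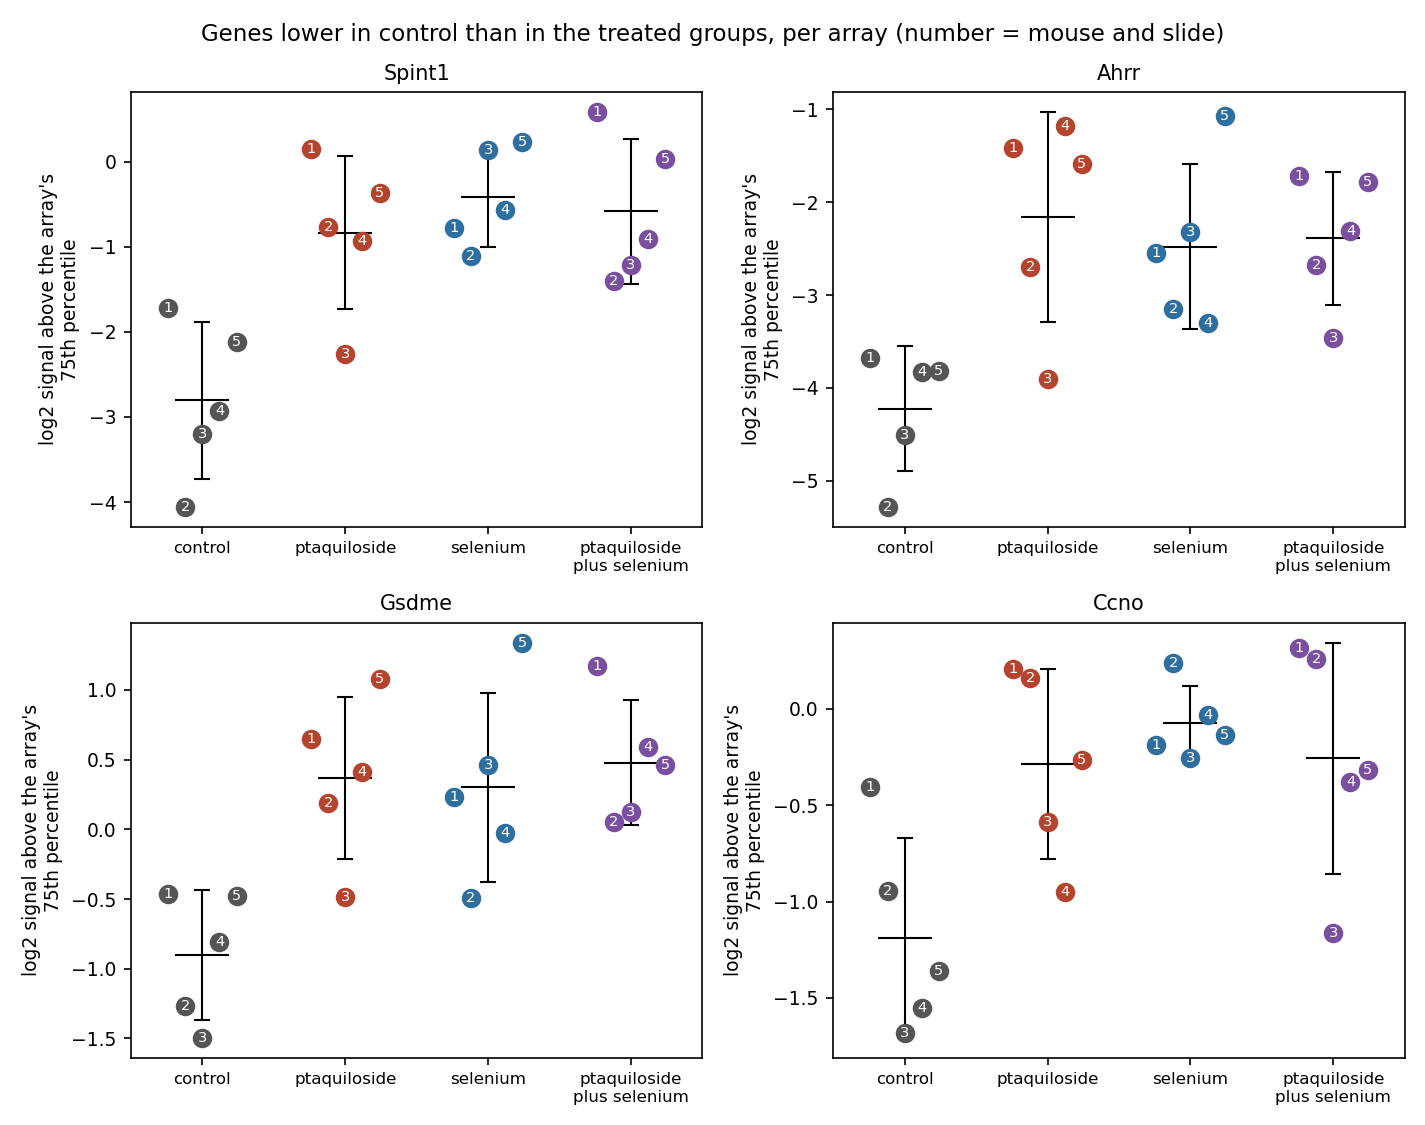
Spint1, Ahrr, Gsdme and Ccno per array as log2 signal above the array's 75th percentile, by group, with the mouse number in each point, black lines for group means and bars for the SD of 5 mice. The control mean is the lowest of the 4 groups for each gene, with Spint1 at -2.81 in control against -0.83, -0.42 and -0.58 in the treated groups.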

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

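The count of regroupings of the arrays, the zinc transporter test and the slide position test were written before their results were seen, and the regroupings within slides and the other tests of this part were chosen only after the result was seen.

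A mouse far from the rest of its group was found in 27 of 236 groups of 5 values tested, where about 11.8 would arise by chance at 1 in 20. In 10 of the 27 that mouse was ptaquiloside mouse 4 and in 4 it was mouse 5 of the group given both compounds. The value given is the gap to the nearest mouse as a share of the group's range. For ptaquiloside mouse 4 it was 0.874 for the share of spots above background, 0.974 for the median correlation with the other arrays, 0.807 for Btk, 0.712 for Ccdc14, 0.774 for Dpys, 0.875 for heat shock genes, 0.759 for NK cytotoxic effectors, 0.734 for NK receptors, 0.760 for p53 genes and 0.770 for selenoproteins. For mouse 5 given both compounds it was 0.817 for the median correlation, 0.868 for Pitpnc1, 0.888 for NK cytotoxic effectors and 0.851 for NK receptors. Ptaquiloside mouse 1 stood apart for the growth factor Csf1 (0.812) and for Xpnpep3 (0.819), and ptaquiloside mouse 3 for Lgals3bp (0.728). Selenium mouse 5 stood apart for the cell cycle (0.750), heat shock genes (0.848) and macrophage markers (0.780), selenium mouse 2 for Unc93a (0.728) and NK receptors (0.773), and selenium mouse 1 for Hcfc1 (0.780). With both compounds, mouse 1 stood apart for the cell cycle (0.804) and mouse 2 for interferon-stimulated genes (0.746). In control, mouse 3 stood apart for Pitpnc1 (0.738) and mouse 2 for selenoproteins (0.767).

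The ptaquiloside difference changed with selenium in 9 gene lists by the test of the interaction with the preset correlation. The median interaction was 1.01 for B cell markers, 0.57 for T cell markers, 0.61 for dendritic cell markers, 0.40 for macrophage and monocyte markers, 0.67 for erythroid markers, 0.34 for calcium and NFAT signalling, 0.38 for Ly49 receptors, -0.50 for interferon-stimulated genes and -0.40 for platelet and megakaryocyte markers. With an estimated correlation 0 of the 9 passed, and without ptaquiloside mouse 4 calcium and NFAT signalling stood at -0.04 and Ly49 receptors at -0.04. The erythroid call ended without control mouse 2, ptaquiloside mouse 3 or 5 or selenium mouse 5, and the macrophage call without control mouse 5 or ptaquiloside mouse 3. Without ptaquiloside mouse 4 the dendritic median was 0.27. Normexp background correction gave 0.23 for erythroid, 0.32 for dendritic cell and 0.23 for macrophage and monocyte markers. Regrouping all arrays without a block gave at least 9 interaction lists in 65 of 100 groupings, the real one included, and up to 21. Regrouping within slides with the slide as a block gave at least the real 10 lists in 73 of 100 and up to 20, so chance is not excluded by either.

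The first pattern weighed is the distance of ptaquiloside mouse 4 from all other arrays. Its median spike-in signal was 1.89 above the lowest of the other arrays, which argues against a failure of labelling, hybridisation or scanning. The 300 probes brightest elsewhere were -4.80 from the mean of its slide mates on the unscaled log2 scale, a loss in the sample's own RNA that fits little or degraded RNA. The other ptaquiloside arrays had a median correlation of 0.972 or more, which argues against the treatment as the reason.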

How the results depend on the processing

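The comparison of control with all treated mice, the methods' t-test, the replicate block without the dimmest 1 or 2 arrays and the list tests with single arrays left out were chosen only after the result was seen, and all other tests here were planned.

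Counts of called genes stayed at 0 under the alternatives except for the methods' t-test with 2 mice replaced by means, which called 7 spots at a 2-fold limit for ptaquiloside against control, and for the interaction, with 0 to 1 call when single arrays were left out. The t-test adds averages as if they were mice. Named genes kept direction and side of the threshold in 2685 of 2698 alternative values and in 2086 of 2100 with an array left out, and 0 became called. Most of these genes were named for a small p or for arrays on the same side of the other group's mean. The choice thus favoured a stable direction, and these counts are not a separate test of it. The cause of the exceptions was not tested, but with the filter on all arrays the values of Arnt and Trat1 match those of another probe of each gene. Arnt against control with ptaquiloside turned from -0.39 to 0.0319 with normexp background correction, 0.33 among probes above background on all arrays, 0.0436 with array weights, 0.0850 in the deposited table, and with a replicate block 0.0555 on 19 and 0.0684 on 18 arrays. Mt3 turned to -0.0343 under median centring for ptaquiloside against control, and for both compounds against ptaquiloside to 0.0258 with normexp, 0.0613 under median centring and 0.0154 with a replicate block on 19 arrays. The interaction turned to -0.58 for Insr under quantile normalization and to -0.25 for Trat1 with the filter on all arrays, and Gp5 to 0.0234 with array weights for both compounds against control. The correlation of the ptaquiloside difference without and with selenium turned to -0.0788 with normexp, -0.255 in the deposited table, and with a replicate block -0.228 on 19 and -0.0827 on 18 arrays.

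Leaving out single arrays gave ranges that crossed 0, and the cause was not tested. They were -0.66 to 0.13 for Arnt with ptaquiloside against control, -0.0260 to 0.84 for Mt1 with selenium, and with both compounds -0.17 to 0.78 for Hspa1b, -0.43 to 0.63 for Mt1 and -0.43 to 0.77 for Mt2. Against ptaquiloside Mt3 ranged from -0.27 to 0.0109, and against selenium Mt1 from -0.78 to 0.17 and Mt2 from -1.02 to 0.0284. At both ends of the Mt1 and Mt2 ranges the array left out was that of a mouse numbered 1. These fits had no slide block, and such mice were high for both genes in every group. Leaving out such a mouse therefore puts part of the slide difference into the value. The correlation ranged from -0.286 to 0.291. Lists called ranged from 5 to 12, 10 to 15, 6 to 12, 7 to 11, 9 to 15 and 8 to 16 in the order ptaquiloside, selenium and both against control, both against ptaquiloside, both against selenium, and interaction, and from 55 to 72 in all.

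Of the 65 list calls 0 held with an estimated correlation, 0 with fry, 0 with a replicate block and estimated correlation, and 0 with both on 19 arrays, while the replicate block alone gave 67. The slide, fixed by the design, coincides with the mouse number, and no donor is shared. After each gene's group mean was subtracted, 24 of 30 same-numbered pairs of arrays from different groups correlated above 0.1, with a median of 0.445. The median was -0.08 for pairs of different numbers. Among the arrays of other groups, 17 of 20 arrays correlated best with one of their own number. The scan date as a block was not run because all 20 arrays carry the same scan day. Signal over background limits the array of ptaquiloside mouse 4, with 36.3% of its spots above it.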

Other observations

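The count of regroupings of the arrays, the zinc transporter test and the slide position test were written before their results were seen, and the regroupings within slides and the other tests of this part were chosen only after the result was seen, as was the comparison of control with all treated mice.

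Set against the mean of the 3 treated groups with the slide as a block and without the array of ptaquiloside mouse 4, 5 genes were lower in control. These were the protease inhibitor Spint1 (2.21 ± 0.30 SE, adjusted p = 0.0189), cyclin Ccno (1.03, 0.0189), the gasdermin Gsdme (1.28, 0.0215), the dynein Dnah2 (0.95, 0.0215, of whose probes another gave -0.04) and the receptor repressor Ahrr (1.79, 0.0215), each higher in treated mice on 5 of 5 slides. On all 20 arrays with the block 1 gene was called, Spint1 (adjusted p = 0.0176), and without the block limma called 0 on 20 or 19 arrays, with 64 and 146 genes at an unadjusted p under 0.05. The other 3 groups, each set against the rest, gave 0 calls.

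In 2 of 100 draws of 1 array per slide, the real one included, at least 5 genes differed from the rest. The other draw, with mice 1 and 5 of the combination and selenium mice 2 to 4, gave 225, of which 51 were lower in the drawn arrays, and points to structure among the arrays. As the comparison was chosen because of these genes, the draws do not settle whether chance gave them. Spike-in signal at the control position differed by -0.14 from the other positions on average (-0.73 to 0.72 on single slides), and position and treatment cannot be told apart. Over the marker lists of other cells the highest median was 0.30, for neutrophils (SD of the members 0.33), and no list covers epithelial or ciliated cells, so another cell type stays open. The 5 other genes of the aryl hydrocarbon response had a median of -0.06, treated minus control (camera p = 0.323 with an estimated correlation). They went both ways: Tiparp (0.84, higher on 5 of 5 slides) and Nqo1 (0.69, 4 of 5) were higher without a call. The receptor Ahr (-0.34) and its partner Arnt (-0.06) were lower. This leaves that receptor open. New mice with groups spread over positions would be needed.

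Mt1 and Mt2 varied more with the mouse number than with treatment. The number accounted for 79.9% of the variance of their mean and the group for 6.60%, with a permutation p of 4.30e-04 for the number. In mice numbered 1 the shift of the less shifted gene exceeded the highest shift of 200 genes of the same brightness by 1.25. This argues against a shift of the whole slide that equally bright genes share. It cannot address a source common to mice of the same number that moves only some genes, since slide and number coincide. The shift was 2.28 for the mean of both genes in the 10 mice given no ptaquiloside, which argues against the toxin as its source. The zinc transporter Slc30a1, another metal-induced gene, was 0.36 higher there, which leaves exposure to a metal open.

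Regroupings of the arrays, 100 per result with the real one included, were scored without a block. Genes at an unadjusted p under 0.05, among those measured on all arrays, were as many in 90 groupings for ptaquiloside against control (262, highest other 4845), 31 for selenium (180, 1285), 92 for both compounds (40, 1557), 82 for both against ptaquiloside (414, 3671), 90 for both against selenium (102, 1200), 74 for the interaction (205, 3262) and 81 for the 4 groups (169, 2770). Lists called were as many in 58 for ptaquiloside (12, 21), 23 for selenium (13, 17), 16 for both compounds (12, 19), 80 for both against ptaquiloside (8, 17) and 25 for both against selenium (11, 15). The correlation of the ptaquiloside difference without and with selenium was as large in 80 (0.0997, highest other 0.720). Chance is excluded for none of them. These groupings mix slide differences into the groups, which the real design keeps apart.

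Regrouping only within slides, with the slide as a block, removes that difference. For the interaction 55 of 100 groupings gave as many genes (363, highest other 2308), and for the 4 groups 40 of 100 (365, 2435), so chance is not excluded there either. Exchanging 2 groups within slides allows 16 groupings, too few for a share under 0.05. As many genes came from 14 for ptaquiloside against control (464, highest other 1330), 2 for selenium (327, 344), 9 for both compounds (71, 159), 13 for both against ptaquiloside (716, 3317) and 9 for both against selenium (197, 794). As many lists came from 9 (12, 16), 3 (13, 13), 5 (10, 13), 11 (10, 16) and 2 (12, 13) in the same order.

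With the methods' t-test and the 2 replaced mice, 12 spots passed for ptaquiloside against control, 7 of them at a 2-fold limit, with 3626 at an unadjusted p under 0.05. With those mice left out 0 passed, with 1126 unadjusted. The spots at the 2-fold limit were above background on few of the 20 arrays. These were 0 for 4631416L12Rik, Btbd16 and Nln, 1 for Kcnmb3, 2 for 4930538E20Rik and 7 for both spots of Col1a1. Mt1 differed by -0.05 on all 5 mice per group and by 1.46 with the replacement, and Mt2 by 0.08 and 1.63. With the replacement neither gene passed, the lowest adjusted p of the t-test being 0.443 for Mt1 and 0.578 for Mt2. Leaving the 2 replaced mice out gave the same 1.46 and 1.63, with 0.968 as the lowest adjusted p of either gene. In both settings ptaquiloside mouse 1 stayed while control mouse 1 of the same slide did not, so slide differences enter these values.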
